A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

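The samples were 35S pre-rRNA, the primary transcript of the ribosomal DNA of Saccharomyces cerevisiae, in particles purified through TAP-tagged Mrd1. Per the labels, 6 libraries form 3 groups of 2. The groups are a strain whose Mrd1 is labelled deltaRDB5, read here as loss of the RNA-binding domain RBD5, treated with the solvent DMSO, the same strain treated with 1M7, and a strain depleted of Erb1 with intact TAP-tagged Mrd1 treated with 1M7. No DMSO library is labelled for the Erb1-depleted strain. 1M7 acylates the 2'-hydroxyl group of flexible nucleotides, and reverse transcriptase stops next to the adduct. Per the labels' protocols, cDNA was made with random hexamers and SuperScript III and 5' adapters were joined with CircLigase II. Reads were aligned with Novoalign, per the submitters' processing notes. Its version is not given in the sources used here.

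All values came from 1 sheet with a line for each of the 6858 nucleotides of the transcript. The deposited values are scores per nucleotide with 1 column per strain, per the file headers, so the libraries of a strain are not told apart. The authors give a raw SHAPE reactivity score, a normalized reactivity score, a posterior probability of modification from the BUM_HMM model, and the smoothed values, Z-factor and standardized difference of a deltaSHAPE comparison. The sheet's note calls the normalized scores 2% to 8% normalized and marks nucleotides without sufficient coverage. In the values, each raw column has a mean of 0, and the normalized score is the raw score times 1 factor per strain (5.21 for the mutant, 4.35 for the Erb1-depleted strain) with negative values set to 0. This set 3219 nucleotides (49.1%) of the mutant and 3189 (48.7%) of the Erb1-depleted strain to 0, so differences were taken between raw scores. How the raw scores were computed, and which control libraries entered those of the Erb1-depleted strain, is not given in the sources used here. The sheet holds no read numbers, so the depth behind a value is unknown.

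The design chosen before the data were examined planned a test on stop counts per library. The sheet holds 1 score per nucleotide and strain instead, so the planned fallback was used, which is a description without a test or p-value. Read and stop counts per library were not analysed here, and the planned ratio of spacer to mature-region reads was not run. A nucleotide was taken as modified at a posterior of at least 0.95. A difference between the strains was called from the raw scores smoothed over 3 nt where the Z-factor was above 0, the difference reached at least 1 SD of all smoothed differences, and at least 3 nucleotides of a window of 5 nt did so. Only called nucleotides that were modified in at least 1 strain were counted. This rule was worked out from the deposited columns. Recomputed, it gave 1646 calls, and 0 differed from those in the authors' deposited table. With the filter on modified nucleotides it gave 390, and 0 differed. The Z-factor was at or below 0 at only 44 nucleotides, with a median of 0.988, so it screened out little. The standardized difference is the smoothed mutant score minus the smoothed Erb1-depleted score, divided by the SD of that difference over the transcript (0.0649).

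Region bounds were taken from the deposited annotation. It starts ITS1 on the last nucleotide of 18S, so the regions were laid end to end by their lengths. With these bounds 7 of 7 modified bases known from mature rRNA fall on the right base, against 5 of 7 with the bounds as deposited. Positions are counted from 1 at the 5' end of the 35S transcript or of the named region. To place a region or list among stretches of the same length, the scores were kept in order and the list was moved along the measured nucleotides through all 6541 rotations, and its percentile among them is given. Neighbouring rotations of a long region share nearly all their nucleotides, so few placements are independent and its percentile is a description. The planned rotation test with adjustment over regions is not reported. Lists fixed before the data were examined were the U3 snoRNA pairing sites (5'ETS 280 to 290, 5'ETS 470 to 480, 18S 1 to 30 and 18S 1100 to 1200), with the names of the hinge sites corrected afterwards and the positions kept, cleavage sites with 5 nt on either side, and bases of mature rRNA that stop reverse transcriptase with 1 nt on either side. The nucleotides named are the 10 largest differences in each direction among those called, at most 1 per 5 nt, the 10 most reactive modified nucleotides of the mutant by the same spacing, every called nucleotide in a U3 pairing site, and the 5 windows of 100 nt with the most calls, ties included. Wilson intervals at 95% treat nucleotides as independent and cover no spread between libraries.

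The calling rule, without the Z-factor and the filter on modified nucleotides, was tested on simulated data. There, 80 segments of 8 nt were shifted by a known raw score against noise with an SD of 0.075, independent between nucleotides. The rule recovered 79 segments at a shift of 0.1 and 80 at 0.2 and at 0.3, with 0 called in the wrong direction. It also called 994, 330 and 129 of 6218 nucleotides outside the segments. Over 20 simulated pairs that differed by noise alone it called 1575 to 1712 nucleotides, because the rule divides by the SD of the difference itself. Broad offsets between the strains were not simulated, so the recovery of segments may not hold for the data. The alternatives were posteriors of 0.9 and 0.99, lists widened by 10 nt, centring on 25S and stops moved by 1 nt, all planned. Added after the data were seen were 4 other scales, a running median over 101 nt taken out of the difference, a threshold of 2, no smoothing, modification in 1 strain only, modification in both strains, no filter on modification, and region bounds as deposited. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.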

Results

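Flexible nucleotides of the 35S pre-rRNA were mapped by SHAPE with the reagent 1M7 in particles purified through Mrd1, an RNA-binding protein of early pre-ribosomes that is needed to make 18S rRNA. Particles with Mrd1 lacking the domain RBD5 (the mutant) were compared with particles from cells depleted of Erb1, a factor needed to make the large subunit, in which Mrd1 is intact. The series title names the question, which is whether rearrangements between the U3 snoRNA and the pre-rRNA depend on Mrd1. U3 is a small nucleolar RNA that pairs with the 5' external transcribed spacer (5'ETS) and with 18S. The mutant was represented by 2 DMSO and 2 1M7 libraries, and the Erb1-depleted strain by 2 1M7 libraries. No strain without either change was included, so effects of RBD5 loss and of Erb1 depletion cannot be told apart. Raw reactivity was given for 6542 of the 6858 nucleotides in both strains, the last at position 6594, so that the 3'ETS has no value. Each strain had 1 value per nucleotide, with its libraries not told apart, and the depth is unknown. No difference could therefore be set against the spread between replicates.

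The first comparison asked where 1M7 marked the pre-rRNA. In the mutant, 1221 of 6609 nucleotides were modified (18.5%, Wilson 95% interval 17.6 to 19.4). Modified nucleotides were densest in 5.8S (51 nucleotides, 32.3%) and 18S (398, 22.1%), followed by 25S (647, 19.4%) and ITS1 (58, 16.1%). They were sparse in the 5'ETS (51, 7.29%) and in ITS2 (16, 6.90%), the spacer between 5.8S and 25S. The share in the 5'ETS lay at percentile 0.251 of all rotations and that in 18S at percentile 99.8. The other regions lay inside the central 95%. For regions this long the rotations overlap heavily, so these percentiles describe placement only. These shares count nucleotides past the posterior threshold and followed mean reactivity only in part. Mean normalized reactivity in the mutant was highest in 5.8S (0.503) and lowest in ITS2 (0.113), as were the shares. It was 0.350 in ITS1, 0.319 in the 5'ETS, 0.291 in 18S and 0.197 in 25S, which is not the order of their shares.

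The 10 most reactive modified nucleotides of the mutant were spread over 4 regions. The highest normalized reactivities were those of A124 (3.07) and A169 (2.86) in the 5'ETS and of U1117 (2.51) and A162 (2.30) in 18S. U219 of ITS1 (2.26), G1780 of 18S (2.24), A396 of the 5'ETS (2.21), U272 of 18S (2.17), A1505 of 18S (2.11) and U2752 of 25S (2.09) followed. G1780 lies beside A1781, a dimethylated base of mature rRNA that stops reverse transcriptase. Whether its value comes from such stops was not tested. All 10 were also modified in the Erb1-depleted strain, with normalized reactivities from 1.48 at U2752 to 2.23 at A124. Adenosines made up 50.5% of the modified nucleotides in the mutant against 26.9% of all nucleotides. By base, 34.7% of A, 18.1% of U, 10.9% of G and 6.63% of C were modified. When stops were moved by 1 nt the share of A fell to 20.8% downstream and 21.1% upstream.

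In the Erb1-depleted strain 1389 of 6583 nucleotides were modified (21.1%, interval 20.1 to 22.1), with the same sparse 5'ETS (73 nucleotides, 10.4%, percentile 1.37) and dense 18S (461, 25.6%, percentile 99.8). ITS2 had 31 modified nucleotides (13.4%) and 25S had 703 (21.1%). Mean normalized reactivity in this strain was again no lower in the 5'ETS (0.318) than in 18S (0.280). Both strains shared 988 modified nucleotides, against 257.6 for independent lists of these sizes, while 233 were modified in the mutant alone and 401 in the Erb1-depleted strain alone. Part of the excess may come from control libraries, if the strains share them. Across nucleotides, which are not independent replicates, raw reactivities of the strains had a Pearson r of 0.868. The mean normalized reactivity of the shared nucleotides was 0.856 in the mutant and 0.838 in the Erb1-depleted strain.

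The second comparison set the strains against each other after 1M7. Differences were called at 390 modified nucleotides, in 171 runs of adjacent positions. Most of these were more reactive in the Erb1-depleted strain (337, 86.4%), and 53 were more reactive in the mutant (13.6%, Wilson interval 10.5 to 17.3). Without the filter on modified nucleotides the split ran the other way, with 897 of 1646 calls higher in the mutant (54.5%) and 749 in the Erb1-depleted strain. At nucleotides modified in neither strain 844 were higher in the mutant and 412 in the Erb1-depleted strain. Each raw column has a mean of 0, so differences toward one strain at modified nucleotides are balanced by differences toward the other elsewhere. The split at unmodified nucleotides is therefore not a separate result and does not show that they were more reactive in the mutant. In the 5'ETS 1 nucleotide was called higher in the mutant and 29 in the Erb1-depleted strain, in 18S 22 and 104, in ITS2 2 and 12, and in 25S 19 and 163. These 4 regions kept more calls higher in the Erb1-depleted strain on each of 4 other scales. The direction of 5.8S and ITS1 turned with the scale. In 5.8S the numbers were 2 and 15, but they were 7 and 0 on each strain's own normalization factor, 8 and 0 at equal SD, 7 and 0 after quantile normalization and 15 and 8 on normalized values with negatives at 0. In ITS1 they were 7 and 14, and on these scales 10 and 7, 11 and 4, 9 and 5, and 20 and 4.

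The split also depends on the scale and on where nucleotides were modified. Raw reactivities spread more widely in the Erb1-depleted strain (SD 0.150) than in the mutant (0.124). The share called higher in the mutant was 27.2% (95 against 254) on each strain's own normalization factor, 29.6% (100 against 238) at equal SD, 27.9% (91 against 235) after quantile normalization and 41.5% (192 against 271) on normalized values with negatives at 0. Before the filter it was between 51.1% and 54.5% on the original and these 4 scales. Calls at nucleotides modified in 1 strain alone went with that strain (41 of 43 for the mutant, 166 of 167 for the Erb1-depleted strain). At nucleotides modified in both strains, 11 were called higher in the mutant and 169 in the Erb1-depleted strain, 45 and 87 at equal SD, and 113 and 116 on normalized values with negatives at 0. With the strains' own factors 12 nucleotides were called higher in the mutant in the 5'ETS and 31 in 25S. Nucleotides called on both the original and another of these scales kept their direction in every case (282, 263, 263 and 291 shared). Such a nucleotide had to reach 1 SD on both scales, which leaves little room for a turn. No region's number of calls or mean difference lay outside the central 95% of rotations. Pairs simulated with noise alone gave 1575 to 1712 calls before the filter on modified nucleotides, against 1646 observed, so the number of calls does not measure how much the strains differ.

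**Figure D1:**
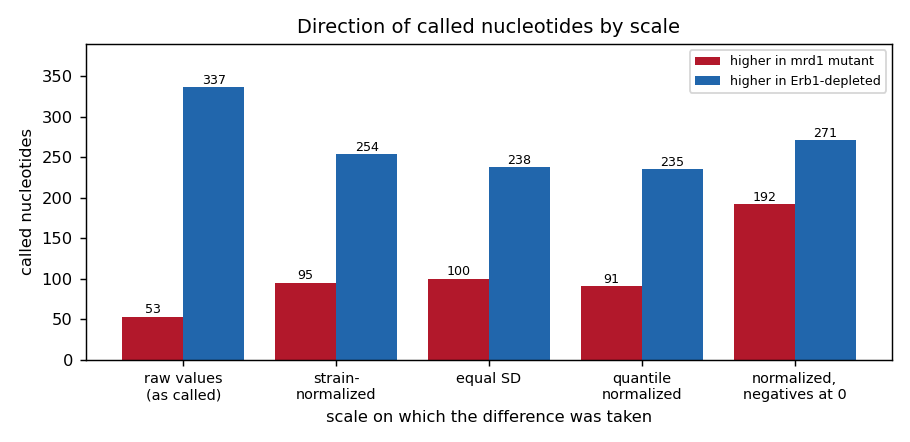
Number of called nucleotides (vertical axis) higher in the mrd1 mutant (red) or in the Erb1-depleted strain (blue) on 5 scales of the difference (horizontal axis), with no error bars because each strain has 1 value per nucleotide. Among these nucleotides, all modified in at least 1 strain, more are higher in the Erb1-depleted strain on each scale, from 337 against 53 on raw values to 271 against 192 on normalized values with negatives at 0, while without the filter on modified nucleotides between 51.1% and 54.5% of calls are higher in the mutant.

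Of the lists, the site in the 5'ETS that pairs with the U3 5' hinge lay outside the central 95% of rotations by its mean difference and by its calls, and the 5' end of 18S and the cleavage sites, which share nucleotides, by their calls. At the U3 5' hinge site (5'ETS 470 to 480, UCAAAGAGUGC), 7 adjacent nucleotides were called higher in the Erb1-depleted strain and 0 in the mutant. Mean normalized reactivity was 0.456 in the mutant and 1.28 in the Erb1-depleted strain, and 1 against 7 nucleotides were modified. A473 had the lowest standardized difference of the transcript, at −4.70, with normalized reactivities of 0.535 in the mutant and 1.86 in the Erb1-depleted strain. The values in the mutant and in the Erb1-depleted strain were 0.414 and 1.70 at A472, 1.15 and 2.18 at A474, 0.490 and 1.57 at G475, and 0.909 and 1.92 at A476. They were 0.392 and 1.17 at G477 and 0.603 and 1.44 at U478. The site's mean standardized difference was −3.40, at percentile 0.321 of rotations, and all 11 nucleotides were negative. With the site widened by 10 nt on either side the mean was −1.49.

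At the site of the U3 3' hinge (5'ETS 280 to 290, AGGAUUUGGUG) the difference had the same direction and was smaller. G281 and G282 were called higher in the Erb1-depleted strain, with normalized reactivities of 0.274 and 0 in the mutant against 1.01 and 0.854. All 11 nucleotides were negative, and 0 against 2 were modified. The mean standardized difference of −1.34 lay at percentile 3.67, inside the central 95% of rotations, and was −0.88 with a running median taken out.

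The 5' end of 18S, which pairs with box A of U3 and later forms a strand of the central pseudoknot, went the other way. Of nucleotides 1 to 30 (UAUCUGGUUGAUCCUGCCAGUAGUCAUAUG), 9 were called higher in the mutant and 0 in the Erb1-depleted strain, and 12 against 5 were modified. Mean normalized reactivity was 0.562 in the mutant and 0.204 in the Erb1-depleted strain. In the mutant and the Erb1-depleted strain respectively, the uridine at position 3 had normalized reactivities of 1.17 and 0.290, C4 1.25 and 0.660, U5 1.78 and 0.550, G6 1.02 and 0.120, and U8 1.06 and 0.0225. U15 had 0.855 and 0.203, G16 0.697 and 0, C17 0.896 and 0.210, and U29 1.14 and 0.754. The number of calls lay at percentile 99.98 of rotations. The mean standardized difference of 1.06 lay at percentile 93.7, inside the central 95%. With a running median taken out it was 0.45, and 7 nucleotides were called higher in the mutant and 1 in the Erb1-depleted strain. The adjoining 5'ETS 601 to 700 had a mean standardized difference of 1.25. It held 0 modified nucleotides in either strain, so no call could be counted there.

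**Figure D2:**
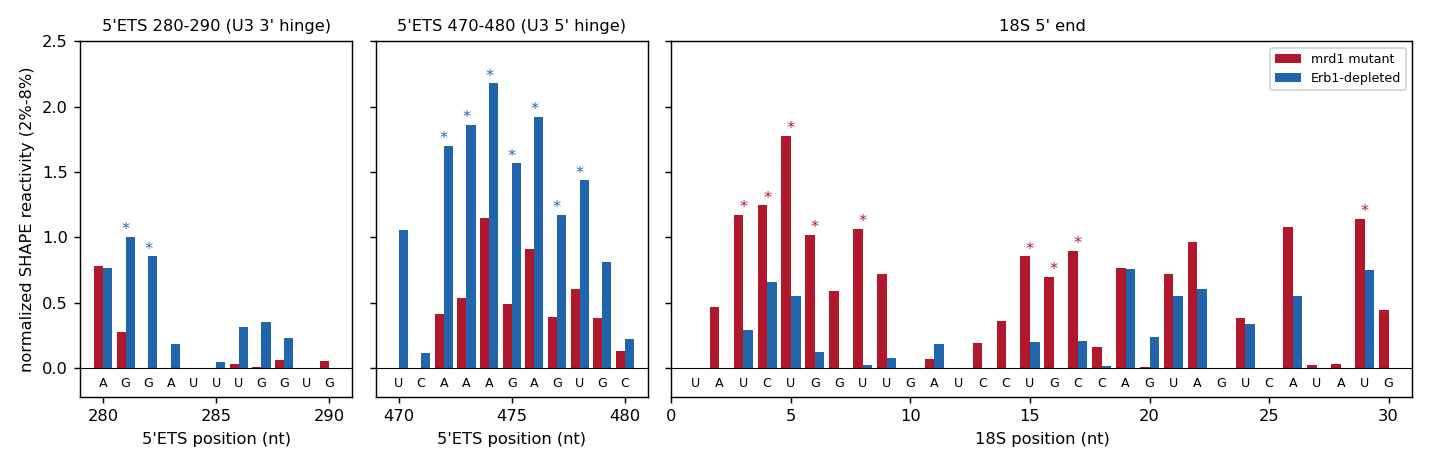
Normalized SHAPE reactivity (vertical axis, 2% to 8% normalized, negative values at 0) of each nucleotide of 5'ETS 280 to 290 (U3 3' hinge site), 5'ETS 470 to 480 (U3 5' hinge site) and the first 30 nucleotides of 18S (horizontal axis) in the mrd1 mutant (red bars) and the Erb1-depleted strain (blue bars), with 1 value per strain and no error bars. Stars mark called nucleotides, which are 2 and 7 higher in the Erb1-depleted strain at the hinge sites and 9 higher in the mutant at the 5' end of 18S.

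The remaining lists held few calls. In 18S 1100 to 1200, which holds the site of U3 box A' and the other strand of the central pseudoknot, A1171 was called higher in the mutant (0.797 against 0.240) and 0 nucleotides in the Erb1-depleted strain. The mean standardized difference there was −0.106 and turned to 0.130 on each strain's own normalization factor, where 6 nucleotides were called higher in the mutant. With a running median taken out, 1 was called higher in the mutant and 6 in the Erb1-depleted strain. Among the cleavage sites, 4 nucleotides were called higher in the mutant (percentile 98.0 of rotations), all beside site A1 and also part of the first 30 nucleotides of 18S. Another 3 were called higher in the Erb1-depleted strain, 2 beside A2 in ITS1 and 1 at the 5' end of 25S, but the numbers were 3 and 7 with a running median taken out. Around bases that carry modifications in mature rRNA, 2 nucleotides of 25S were called higher in the Erb1-depleted strain (1 after quantile normalization). They flank m1A2142 and m3U2634, which themselves were modified by the posterior in neither strain. The mean standardized difference of this list was −0.683 (percentile 4.62), with 2 positive and 17 negative, and −0.81 with a running median taken out (percentile 2.04, outside the central 95%). The adjacent dimethylated adenosines of 18S, A1781 and A1782, were modified by the posterior in both strains, with normalized reactivities of 1.66 and 1.69 in the mutant and 1.48 and 1.41 in the Erb1-depleted strain.

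Along the transcript, windows of 100 nt with many calls lay mostly in 18S and 25S and were higher in the Erb1-depleted strain. These 2 regions hold 1800 and 3297 of the 6542 nucleotides measured in both strains, so most windows lie there by length alone. The share of measured nucleotides called was highest in 5.8S (10.8%, against 7% in 18S and 5.52% in 25S). The window with most calls was 18S 601 to 700 (2 higher in the mutant, 18 in the Erb1-depleted strain), followed by 25S 1450 to 1549 (0 and 19), 5.8S 40 to 139 (2 and 15, but 7 and 0 at equal SD) and 25S 850 to 949 (0 and 14). Tied next were 18S 1401 to 1500, 18S 1701 to 1800 and 25S 2350 to 2449, each with 13 higher in the Erb1-depleted strain. The order depends on the scale. At equal SD the numbers higher in the Erb1-depleted strain were 14 in 18S 601 to 700, 11 in 25S 850 to 949, 10 in 25S 1450 to 1549 and in 18S 1701 to 1800, 7 in 18S 1401 to 1500 and 3 in 25S 2350 to 2449. In 25S 1450 to 1549 the numbers were 1 and 4 with a running median taken out. Of 17 windows with at least 10 calls, 2 had more calls higher in the mutant. They were 18S 1 to 100 (11 and 0, or 10 and 4 with a running median taken out) and 25S 250 to 349 (6 and 5, but 4 and 16 with a running median taken out).

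**Figure D3:**
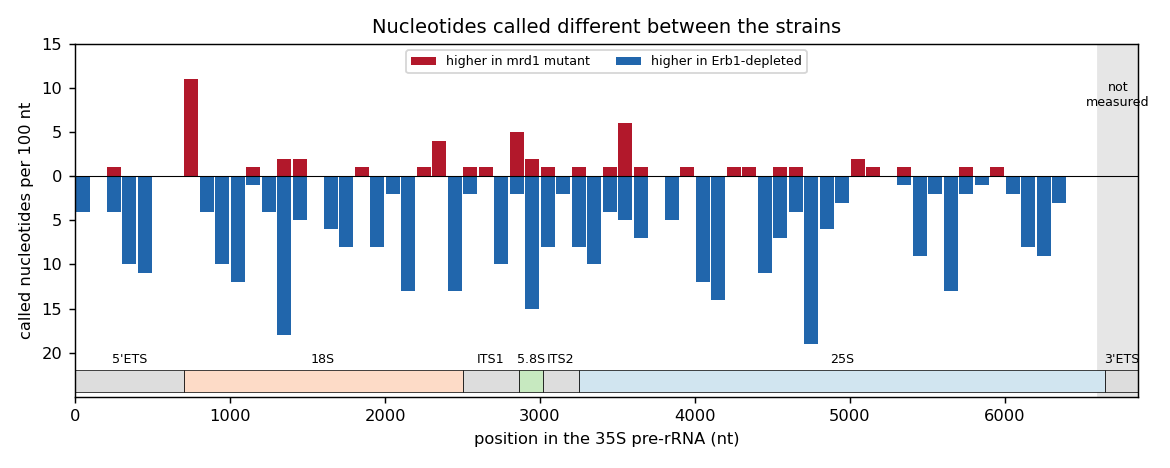
Called nucleotides per window of 100 nt (vertical axis) along the 35S pre-rRNA (horizontal axis, nucleotides from the 5' end), upward in red where higher in the mrd1 mutant and downward in blue where higher in the Erb1-depleted strain, with the regions drawn to scale below. The start of 18S stands out with 11 calls higher in the mutant and 0 in the Erb1-depleted strain, and the grey part at the 3' end has no values. Only modified nucleotides are counted, so windows without any, such as 5'ETS 601 to 700 (mean standardized difference 1.25), hold 0 calls.

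The highest standardized difference of the transcript, 4.05 at nucleotide 6537, lay in 25S 3250 to 3349, which held 0 modified nucleotides. Among called nucleotides modified in at least 1 strain, the largest differences toward the mutant began with G6 of 18S (standardized difference 2.75). U93 of 5.8S followed with 2.02 (normalized reactivity 0.978 in the mutant and 0.0183 in the Erb1-depleted strain), then G16 and A485 of 18S (0.640 and 0 at A485) and A219 of ITS2 (1.70 and 0.0894). A307 of 25S had 1.31 in the mutant and 0.773 in the Erb1-depleted strain, C1619 of 18S 0.895 and 0.291, G687 of 18S 1.48 and 0.949, A312 of ITS1 0.866 and 0.284, and A1842 of 25S 0.418 and 0.

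Toward the Erb1-depleted strain, A473 was followed by U601 of 25S (standardized difference −4.63, normalized reactivity 0.825 in the mutant and 2.09 in the Erb1-depleted strain), A302 of the 5'ETS (−4.51, 0 and 0.939) and A578 of 25S (−3.74, 0.503 and 1.56). A1755 of 18S, an adenosine of the decoding site in the mature subunit, had 1.62 in the mutant and 2.15 in the Erb1-depleted strain. After it came G282 of the 5'ETS, G59 of 25S (0 and 0.666), U478 of the 5'ETS, C596 of 25S (1.28 and 1.59) and G156 of 25S (0 and 0.755). All 20 kept their direction on the strains' own factors, at equal SD, after quantile normalization and with a running median taken out. With the running median taken out, A1842 of 25S (0.70) and C596 of 25S (−0.29) were no longer called, and G687 of 18S had 1.02, U601 of 25S −2.79 and A578 of 25S −1.78. U601, A578 and C596 lie in a window, 25S 550 to 649, whose mean raw difference was −0.154.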

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

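The 4 other scales, the running median, the threshold of 2, the calls without smoothing, the calls modified in 1 strain only or in both, the calls without the filter on modification and the deposited region bounds were chosen after the data were seen. At posteriors of 0.9 and 0.99 the counts of modified and of called nucleotides stayed within 1.5 times of those reported. The number called higher in the mutant, 53, was 95 on each strain's own normalization factor, 192 on normalized values with negatives at 0, 100 at equal SD and 91 after quantile normalization. With a threshold of 2, 41 nucleotides were called, 4 higher in the mutant and 37 in the Erb1-depleted strain, because fewer pass a stricter threshold. With modification in 1 strain only, 210 were called, 168 of them higher in the Erb1-depleted strain, and with modification in both strains 180, of them 11 higher in the mutant and 169 in the Erb1-depleted strain, because fewer nucleotides qualify. Without the filter on modification 1646 were called, and more were higher in the mutant (897) than in the Erb1-depleted strain (749). The cause of the other changes was not tested. No nucleotide called here was called in the opposite direction in another setting. Where only the posterior, the threshold or the filter on modification changed, a turn was impossible, because the difference was the same. On the other scales it had little room, because a nucleotide had to reach 1 SD on both scales. Of the other values of regions, lists, bases and named nucleotides, 33 stayed the same and 19 moved under planned settings, 15 of these with stops moved by 1 nt. Under added settings 148 stayed the same, 20 moved and 2 were no longer called. No paired analysis was possible because each strain has 1 score per nucleotide and its libraries are not told apart. For the same reason the edgeR and DESeq2 tests, TMM, the unscaled fit, coverage filters, fits of 4 libraries, each replicate left out in turn, the adjusted p threshold, the pseudocount and the ratio of spacer to mature-region reads were not run. The threshold on log2 ratios was not run because the scores are not log ratios. Depth is unknown, so its limit on single nucleotides could not be given.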

Other observations

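The tests at equal SD, of RNA ends at site A1 and of reads over windows were chosen only after the result was seen. Calls by base were as follows. Of 318 G modified in at least 1 strain, 3 were called higher in the mutant and 87 in the Erb1-depleted strain (13 and 52 at equal SD), and of 769 A, 21 and 173 (35 and 127). U had 20 and 67 of 435 (39 and 54 at equal SD, but 61 and 52 on normalized values with negatives at 0), and C had 9 and 10 of 100, turning to 13 and 5 at equal SD. The share of all G that was modified was 10.9% in the mutant and 16.4% in the Erb1-depleted strain, against 6.63% and 5.69% of C. In the decoding site of 18S, A1756 beside A1755 was the second most reactive modified nucleotide of the Erb1-depleted strain, with a normalized reactivity of 2.23 against 1.69 in the mutant. It is named here after its value was seen. Broad stretches also differed in level. The mean raw difference, mutant minus Erb1-depleted, ran from −0.154 in 25S 550 to 649 to 0.120 in 25S 3250 to 3349, where 53 nucleotides were measured. It was 0.0811 in the last 100 nt of the 5'ETS and −0.0630 in 5'ETS 401 to 500, and 6 of 66 windows reached 0.05 in either direction. Whether such offsets go with fewer reads is undecided, with a Spearman rho of 0.135 over the 66 windows between the size of the offset and the error term of the comparison (percentile 86.2 of rotated windows).

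Among called nucleotides that were modified in at least 1 strain, most were more reactive in the Erb1-depleted strain, while over all 1646 calls 897 were higher in the mutant. These splits are not independent, because each raw column has a mean of 0. A wider spread of the Erb1-depleted strain's raw values stays open as an explanation, with a share higher in the mutant of 13.6% on raw values and 29.6% at equal SD. A different shape of the value distributions stays open too, with 27.9% after quantile normalization. Neither can be told apart from a difference between the strains, because the filter on modification follows the direction of the call (41 of 43 calls modified in the mutant alone, 166 of 167 in the Erb1-depleted strain alone), a link that moving the modified positions along the transcript breaks. Background stops of the Erb1-depleted strain, for which no solvent control is labelled, were not tested.

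The U3 5' hinge site (5'ETS 470 to 480) was less reactive in the mutant than in the Erb1-depleted strain. A broad offset between the strains in that part of the transcript is argued against by the mean standardized difference of −3.35 with the running median taken out, below all but the lowest 0.0153% of rotations. A different shape of the distributions is argued against by −3.35 after quantile normalization. Strain-specific background and a difference between the strains were not tested and stay open. Such a difference could come from RBD5 loss or from Erb1 depletion, which the design cannot separate.

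The 5' end of 18S was more reactive in the mutant than in the Erb1-depleted strain, and here too RBD5 loss and Erb1 depletion cannot be separated. With the running median taken out 7 nucleotides were called higher in the mutant (percentile 99.88 of rotations) and 1 in the Erb1-depleted strain. This does not decide whether a broad offset caused the calls. The adjoining 5'ETS 601 to 700 had a mean standardized difference of 1.25 and 0 modified nucleotides, so no call could be counted there. If an offset ends near the start of 18S, the running median may take out only part of it. After quantile normalization 9 nucleotides were called higher in the mutant (percentile 99.97), so the shape of the distributions is not the whole cause of the number of calls. The mean standardized difference was 0.45 with the running median taken out and 1.37 after quantile normalization. For this mean, neither an offset nor the shape can be told apart from chance placement, because the mean of 1.06 already lay inside the rotations. If the scores counted ends, more RNA ends from cleavage at site A1 in the mutant would be argued against by the raw differences of −0.0250 at the first nucleotide of 18S (−0.0960 in the mutant, −0.0710 in the Erb1-depleted strain) and −0.114 just before it (−0.0435 and 0.0703). That explanation stays open, because ends stop reverse transcriptase with or without 1M7 and how controls entered the scores is not given in the sources used here, and strain-specific background and a difference between the strains were not tested and stay open too.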
